A study of Cercocebus atys with 16 samples.

How the data were processed

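The samples were 16 arrays with 2 colours, 4 for each of 4 sooty mangabeys (Cercocebus atys) infected with SIV. Per the labels, double-negative T cells were isolated with magnetic beads from blood mononuclear cells at a purity above 98%, rested overnight and stimulated for 4 hours with anti-CD3 and anti-CD28, given in the labels as 3 and 1 mg/ml. Labelled cRNA was hybridised to an Agilent array designed on the rhesus macaque, a related species, so a probe can bind mangabey RNA less well where the sequences differ. The labels name Cy3 for channel 1 and Cy5 for channel 2, and each animal had a stimulated against unstimulated array in each dye orientation, a stimulated self-self array and an unstimulated self-self array. On 1 ratio array of FNV the title names stimulated RNA in channel 2 and a characteristic names unstimulated RNA; the title and the study's stated dye flip were followed, and leaving that array out was an alternative.

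The authors deposited scanner output per array: spot and local background intensity on a linear scale, not normalised, with flags for outliers, saturation and signal well above background, from Agilent Feature Extraction 10.7.3.1 per the file headers. The files also hold, per the file headers, a log10 ratio of red over green after the software's own background subtraction, detrending and dye normalisation. A table of the whole series gives the authors' log2 ratio of stimulated over unstimulated per animal, called normalised in its header; its method is not given in the sources used here, and limma and Agilent Feature Extraction are named in the submitters' processing notes without a role. Set against the ratios computed here, its columns correlated across features at 0.92 for FNV, 0.88 for FKN, 0.89 for FBR and 0.90 for FTV, with slopes of 1.20 to 1.27 and medians of 0.06, 0.00, 0.00 and -0.01, so its direction is stimulated over unstimulated and its centring and background method stay unknown. Of its 41687 identifiers, 40631 matched an accession on the array, and it served as an alternative for named genes.

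Ratios were computed here in R 4.3.3 with limma 3.58.1, statmod 1.5.0 and version 1.17.8 of data.table, and drawn with Python 3.11.15 and matplotlib 3.10.9. Mean spot signals were corrected with normexp at an offset of 50 and normalised within each array by loess, with control and outlier spots at weight 0. Outlier spots, at most 51 per array, were then left out, no spot was saturated, and no pair of arrays held an identical channel. Spots of one probe were averaged, the sign of one dye orientation was turned, and the 2 ratio arrays of an animal were averaged, since they hold the same 2 RNAs, so n = 4 animals. A probe was kept where it was well above background on both ratio arrays of an animal in the channel of one condition, in at least 2 animals. Levels used Aquantile normalisation between arrays and the mean of the 4 channels of an animal and condition.

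The arrays carry 2 editions of the probe annotation, which give different gene names for 8125 of 43803 spots (18.5%); the newer, on the 12 later arrays, was used. Of the distinct probes, 18177 took their gene symbol from the gene name column, 1367 from the description, 516 from the older edition and 162 from aliases, which are older or accession-like names, and 23381 stayed unnamed. Many of these aliases rest on a description that says the transcript is like the gene, and the aliases for PTGDR2, KLRK1 and FCGR3A were added after the value of PTGDR2 had been seen. In the reference table for the Caty_1.0 assembly, 7945 of 9175 tested symbols occur and 0 of 40631 array accessions, so it was used for no name and no coordinate. Coordinates are those the files give on rheMac2. The tested features were 1 probe per symbol, the one with the highest mean intensity over the 16 arrays, and every probe without a symbol; with every probe tested, 49 of 102 named genes had more than 1, and in 0 of them did probes pass in opposite directions. A fold was to be given as a lower bound where a probe was well above background in no channel of a condition, which held for 0 of the 102 named genes. Only some channels were well above background for IL21 (3 of 8 unstimulated), IL13 (6 of 8 unstimulated), FCGR3A (5 of 8 stimulated) and FGFBP2 (6 of 8 in each condition), so the sizes given for these are less certain.

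The stimulation response was tested against 0 with limma's lmFit and eBayes on the 4 per-animal ratios, with Benjamini-Hochberg adjustment over all tested features, and features with an adjusted p under 0.05 are said to have risen or fallen. CD4 status was tested as low minus normal, 2 animals against 2, on the responses, the unstimulated levels and the stimulated levels. The 31 gene lists held 570 genes, of which 527 matched a probe, 14 stood in more than 1 list and the rest were not analysed here; 30 lists with at least 3 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry. With an estimated correlation, camera also takes its degrees of freedom from the fit of the 4 animals, which leaves little power. A call lost in that setting therefore does not by itself show that the genes of a list vary together. The named genes were the 15 largest rises and 10 largest falls with one sign in 4 animals, up to 2 rises and 2 falls of each list, and 15 genes fixed by name. For CD4 status they were the 5 largest passing each way or, with none passing, the 3 with the smallest p, and the coreceptors. The design, the lists, this rule and most alternatives were set before the data were examined.

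Stimulated and unstimulated samples were paired because they came from the same animal and shared an array. Deviations of stimulated and unstimulated levels from the mean of the 4 animals correlated across features at 0.83, 0.77, 0.83 and 0.77 within FNV, FKN, FBR and FTV, against at most 0.36 between animals. Each animal had its own slide, so slide and animal cannot be told apart. In the fits 2 scan batches were set by the annotation edition of the arrays, with FNV alone in the earlier. The batch was handled by leaving FNV out and as a term. Neither fit can tell an effect of the batch apart from a trait of FNV.

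On simulated data over 16892 features, the stimulation test found 28 of 50 changes of 0.5 on the log2 scale, 48 of 50 of 1, 50 of 50 of 2 and 49 of 50 of 3, with 12 unchanged features among 187 called. The test of unstimulated levels by CD4 status found 0 of 50 differences of 1, 4 of 50 of 2, 23 of 50 of 3 and 31 of 50 of 4, with 0 unchanged features called. A planted shift of a gene list was found and 0 of 30 unshifted lists were called. The simulated genes varied independently, so this cannot show whether the preset correlation suits lists whose genes vary together. The changes of single genes were planted in brighter probes only, so recovery among dim probes was not tested.

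On 3 self-self arrays some spots lay more than 100 units below their local background, 3 spots each on the stimulated arrays of FNV and FKN and 37 on that of FTV. The ratio arrays had none. Leaving these spots out was an alternative added after the data were seen, as were the scan batch term, levels from the ratio arrays alone, the estimated correlation without each animal and the gene lists in the CD4 comparison. The alternatives set beforehand were no background subtraction, the scanner software's ratios, median centring, no filter and a filter in all 4 animals, every probe, the self-self arrays alone, no pairing, the animal as a random block, a trended robust prior, quantile normalisation of levels, and leaving out each animal.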

Results

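Gene expression was measured in double-negative T cells, which carry CD3 and lack CD4 and CD8, from the blood of 4 sooty mangabeys. All 4 animals were infected with SIV, the simian immunodeficiency virus, and their CD4 status was labelled normal in FNV and FKN and low in FBR and FTV. Cells of each animal were left unstimulated or stimulated for 4 hours with antibodies to CD3 and CD28, which engage the T cell receptor and its main costimulatory receptor. Each animal had 4 arrays with 2 colours: 2 set stimulated against unstimulated RNA with the dyes exchanged, and 2 self-self arrays held the same RNA in both channels. Of the 43803 non-control spots, 57% to 65% were well above background in a channel of the 12 arrays of FKN, FBR and FTV. On the 4 arrays of FNV, which were scanned in an earlier batch, the range was 33.3% to 64.8%. The number of arrays and animals limited the precision, with a median SD between animals of 0.16 (log2) over the tested features.

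The first comparison asked which transcripts changed when the cells were stimulated. The largest rises were in cytokine genes of the Th2, Th17 and Th1 programmes. IL5, the eosinophil growth factor, rose by 6.0 ± 0.58 on the log2 scale (SD, n = 4; 63.8-fold), IL22, which acts on epithelial cells, by 5.65 ± 0.52 (50.2-fold), and IFNG, the macrophage-activating interferon, by 5.51 ± 0.70 (45.5-fold). PTGS2, the inducible cyclooxygenase, rose by 4.87 ± 0.52, IL4 by 4.62 ± 0.44, and IL2, the T cell growth factor, by 4.58 ± 1.58. The limma adjusted p was 0.000542 for IL5, IL22 and IL4, 0.000567 for IFNG and PTGS2, and 0.00364 for IL2, and each of these 6 genes was higher in 4 of 4 animals. Among the 15 largest rises were also the chemokine gene CCL20 (4.55), the NF-kB inhibitor TNIP3 (4.03), IL10 (3.92), which restrains inflammation, CXCL11 (3.79), XCL1 (3.78), IL13 (3.40; unstimulated signal well above background in 6 of 8 channels), the kinase RIPK2 (3.22), IL17A (3.21), which recruits neutrophils, and the costimulatory receptor TNFRSF9 (3.20).

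Among the 10 largest falls, CALHM2, a channel gene, fell by 3.51 ± 0.33 (SD, n = 4; 11.4-fold) and TMEM204 by 3.30 ± 0.78. PIK3IP1, an inhibitor of PI3 kinase, fell by 3.18 ± 0.57, and PTGDR2, the prostaglandin D receptor of Th2 cells, by 3.05 ± 0.36. The others were SYTL2 (-3.13), CSPG5 (-3.02), the cytokine gene IL16 (-2.98), the acid-sensing channel gene ACCN2 (-2.97), the protease gene HTRA1 (-2.86) and TSC22D3 (-2.78), a glucocorticoid-induced gene. The limma adjusted p ranged from 0.000542 for CALHM2 and TSC22D3 to 0.00149 for CSPG5, and each was lower in 4 of 4 animals.

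Of the 49 named genes with more than 1 tested probe, 23 had another probe whose log2 value differed by over 1.5 times. This factor compares log2 values, so folds within it can still differ by more. TNIP3, with probes at 4.03 and 2.72, lay within it. Among the genes that fell, these were -0.66 for CALHM2, -1.66 for CSPG5, -1.21 for PIK3IP1, -1.59 for CD79B, -0.42 for CR2, -0.79 for CXCR3, -0.50 for VCAN, -0.44 for HBA2 and -0.81 for RPL13A. Among the genes that rose, they were 1.72 for PTGS2, 2.14 for XCL1, 0.70 for SLC16A1, 0.62 for PSAT1, 0.86 for BCL2L1, 0.82 for SREBF1, 0.31 for BTG1, 0.47 for PGK1 and 0.30 for TRDC. The other probe did not pass in 5 genes, ACCN2 (-0.07), IL10 (0.85), HOPX (0.20), IRF9 (-0.20) and SOX13 (0.00). The authors' ratios ran larger than those computed here, with slopes of 1.20 to 1.27, so the folds depend on the processing. TNFRSF9 had a mean of 4.78 in their table, against 3.20 here, and IL13 of 4.60, against 3.40. Both log2 values were larger by less than 1.5 times, while the folds differed by more than that. In the authors' table, 13 of 95 named genes had a mean log2 ratio over 1.5 times away from the value here, and 0 passing genes had the opposite sign. Of these, 11 passed here: IL21 (4.14), CD69 (3.13), CD160 (1.77), FCER2 (0.87), LAMP3 (0.84), TRDC (0.74), CD8B (0.39), SOX13 (-2.03), FGFBP2 (-1.39), AURKA (-0.86) and FCGR3A (-0.64); CD4 (0.08) and FOXP3 (0.09) did not.

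On the rheMac2 build to which the files place the probes, the IL5 probe lay on chromosome 6 at 128945942 to 128946001, near that of IL4 on chromosome 6 at 129090299 to 129090358 and that of IL13 at 129067867 to 129067926. The IL22 and IFNG probes both lay on chromosome 11, at 65239508 to 65239567 and at 65144018 to 65144077. The IL2 probe lay on chromosome 5 at 114846887 to 114846946 and that of IL21 on the same chromosome at 114981640 to 114981699. The CALHM2 probe lay on chromosome 9 at 103140106 to 103140165, and the PIK3IP1 probe on chromosome 10 at 75165360 to 75165419. Exon and UTR positions were not analysed here.

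**Figure D1:**
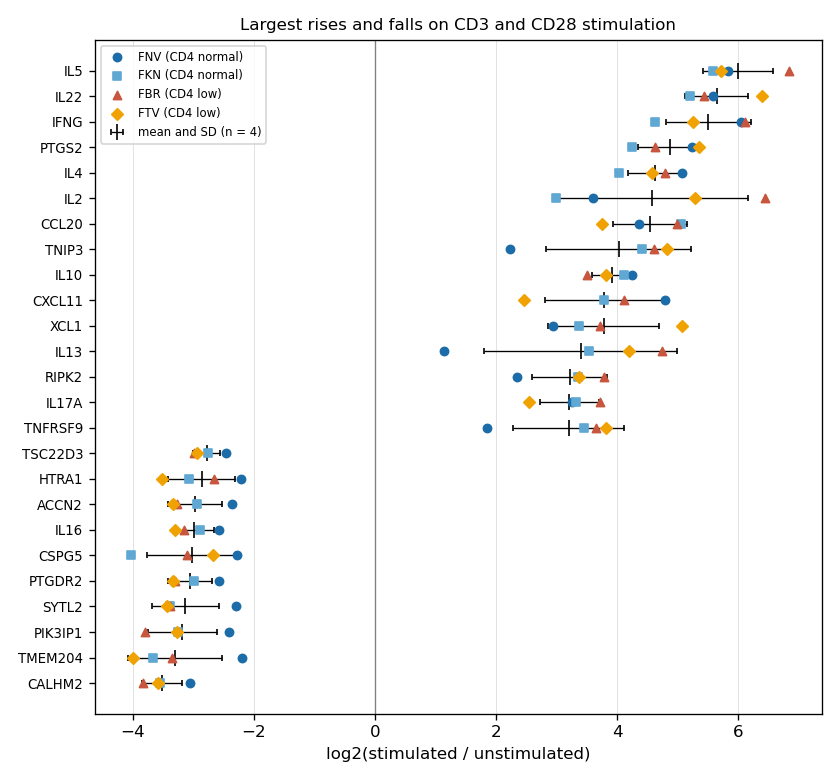
Log2 ratio of stimulated over unstimulated RNA (x axis) for the 15 named genes with the largest mean rise and the 10 with the largest mean fall (y axis), with 1 symbol per animal and the mean and SD of the 4 animals as a vertical mark and bar. IL5 has the highest mean, 6.0, CALHM2 the lowest, -3.51, and in each of these genes all 4 animals lie on one side of 0.

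Over 22655 tested features, of which 9175 had a gene name, 9081 passed the limma test at an adjusted p under 0.05. Of these, 4330 were higher and 4751 lower after stimulation, 8989 had the same sign in 4 of 4 animals, and 1545 changed at least 2-fold, 800 higher and 745 lower. Without FKN the count was 4868, without FBR 5194 and without FTV 5946, while the later scan batch alone, which is the fit without FNV, gave 11390 and scan batch as a term 11500. Median centring of the arrays gave 4048 features, and the self-self arrays alone gave 6842 with the pairing by animal and 1946 without it (no replicate block), of which 976 changed at least 2-fold; the scanner software's ratios gave 3295 changes of at least 2-fold.

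Most measured genes of the Th1, Th2 and Th17 lists rose on stimulation. Of 14 measured Th1 genes, 10 rose, led by IFNG and IL2, while CXCR3, a chemokine receptor of Th1 cells, fell by 1.64 and 3 genes did not pass (10 and 1 adjusted over the list alone). TNF, an inflammatory cytokine gene of this list, rose by 2.90 ± 0.23 (SD, n = 4; limma adjusted p = 0.000542). Of 13 measured Th2 genes, 9 rose, led by IL5 and IL4, while PTGDR2 fell and 3 did not pass (11 and 1 adjusted over the list alone). Of 13 measured Th17 genes, 11 rose, led by IL22 and IL17A, while CTSH, a cathepsin gene, fell by 1.20 and 1 did not pass (11 and 1 adjusted over the list alone). Against all other features, the camera test gave adjusted p = 0.000824 for the Th1 list, 0.00034 for Th2 and 0.000131 for Th17, with list medians of 0.77, 0.83 and 1.07. With an estimated correlation these became adjusted p = 0.405, adjusted p = 0.272 and adjusted p = 0.345. With the scanner software's ratios the median was 1.17 for Th1 and 3.66 for Th2.

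Markers of follicular helper cells, which assist B cells, rose in 8 of 14 measured genes and 6 did not pass (8 adjusted over the list alone). They were led by CD40LG, the ligand of the B cell receptor CD40 (2.53 ± 0.42), and the costimulator ICOS (2.18 ± 0.34), and IL21 of the same list rose by 1.85 ± 0.89 (SD, n = 4; limma adjusted p = 0.0109). The size of the IL21 change is uncertain, as its unstimulated signal was well above background in only 3 of 8 channels and the authors' table has a mean of 4.14. Of 12 measured regulatory T cell markers, 6 rose, led by IL10 and CTLA4 (2.80 ± 0.34), an inhibitory receptor, and 6 did not pass (6 higher and 1 lower adjusted over the list alone). FOXP3, the defining factor of regulatory T cells, had 0.03 ± 0.04 (adjusted p = 0.634). The camera adjusted p was 0.000668 for the follicular helper list (median 0.57; adjusted p = 0.345 with an estimated correlation) and 0.00763 for the regulatory list (median 0.46, or 0.94 with the scanner software's ratios; adjusted p = 0.345 with an estimated correlation).

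Chemokine genes, which direct the migration of leukocytes, rose in 11 of 18 measured members and 7 did not pass (11 adjusted over the list alone). CCL20, the ligand of CCR6, and CXCL11, a ligand of CXCR3, rose most. The list median was 1.49, with camera adjusted p = 0.00061 and adjusted p = 0.272 with an estimated correlation. In the same contrast the monocyte list had a median of -0.60 (adjusted p = 0.426 with an estimated correlation), or -0.23 without FNV, and the animal with the highest chemokine median, FNV at 2.34, had the lowest monocyte median, -1.32.

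Surface markers of T cell activation rose in 18 of 20 measured genes and 2 did not pass (19 higher and 1 lower adjusted over the list alone). The leading genes were TNFRSF9 and CTLA4, and IL2RA, the high-affinity subunit of the IL-2 receptor, rose by 2.55 ± 0.44 and the early activation antigen CD69 by 1.84 ± 0.48 (SD, n = 4; limma adjusted p = 0.000766 and 0.00182). Of 20 measured genes of the immediate early list, which holds AP-1, EGR and NR4A factors and a few others, 14 rose, 1 fell and 5 did not pass (15 and 1 adjusted over the list alone). IRF8, an interferon regulatory factor outside those families (2.71 ± 1.00), and BATF3, an AP-1 family member (2.39 ± 0.54), led the rises, while JUN, an AP-1 subunit, fell by 1.58 ± 0.92 (SD, n = 4; limma adjusted p = 0.0196). The camera adjusted p was 5.16e-09 for the activation markers (median 1.46; adjusted p = 0.299 with an estimated correlation) and 1.9e-06 for the immediate early factors (median 1.38; adjusted p = 0.345 with an estimated correlation).

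Target genes of NF-kB, a transcription factor of inflammation and survival, rose in 17 of 23 measured members and 6 did not pass (17 adjusted over the list alone). BIRC3, an inhibitor of apoptosis, rose by 2.14 ± 0.52, and the survival gene BCL2A1 by 2.01 ± 0.45. Feedback phosphatases and SOCS proteins damp kinase and cytokine signals. Their list also holds PIM kinase, RGS, SPRY and SPRED genes, CBLB and RCAN1. Of its 22 measured members, 13 rose and 9 did not pass (13 higher and 1 lower adjusted over the list alone). The rises include PIM1, PIM2, PIM3, RGS1, CBLB and SPRY1, so the count is not one of phosphatases and SOCS proteins alone. CISH (2.68 ± 0.95) and the phosphatase gene DUSP5 (2.48 ± 0.70) led these. The camera adjusted p was 3.73e-05 for the NF-kB list (median 0.69; adjusted p = 0.272 with an estimated correlation) and 6.7e-05 for the feedback list (median 1.10; adjusted p = 0.375 with an estimated correlation).

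Ribosome biogenesis was the only list of which every measured gene rose, 29 of 29 (29 adjusted over the list alone). DDX21, an RNA helicase of the nucleolus, rose by 2.50 ± 0.37 and RRP12, a factor of ribosome export, by 2.30 ± 0.43 (SD, n = 4; limma adjusted p = 0.000639 and 0.000877). The list median was 1.32, with camera adjusted p = 3.69e-16 and adjusted p = 0.331 with an estimated correlation. Of 21 measured heat shock proteins and chaperones, which fold proteins, 18 rose and 3 did not pass (18 adjusted over the list alone), among them HSPA8 (1.62 ± 0.20) and HSP90AB1 (1.61 ± 0.42). Their camera adjusted p was 2.76e-08 (median 1.04; adjusted p = 0.405 with an estimated correlation).

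Genes of amino acid transport, one-carbon metabolism and ATF4, the factor of the amino acid response, rose in 12 of 23 measured members, fell in 2 and did not pass in 9 (13 and 2 adjusted over the list alone). MTHFD2, a mitochondrial one-carbon enzyme, rose by 2.21 ± 0.50 and PSAT1, of serine synthesis, by 1.97 ± 0.67, while DDIT3, a stress-induced factor of the ATF4 arm, and SLC7A11, the cystine transporter, fell by 0.51 and 0.50. Of 21 measured genes of cholesterol synthesis and uptake, 12 rose, 2 fell and 7 did not pass (12 and 2 adjusted over the list alone). SREBF1, a regulator of lipid synthesis, rose by 1.75 ± 0.48 and STARD4, a sterol carrier, by 1.10 ± 0.60, while ABCG1, which exports cholesterol, fell by 1.22 ± 0.22 and PMVK, a kinase of the mevalonate pathway, by 0.86 ± 0.20. The camera adjusted p was 0.00558 for the amino acid list (median 0.53, or 0.80 with the scanner software's ratios; adjusted p = 0.426 with an estimated correlation) and 0.00161 for the cholesterol list (median 0.53; adjusted p = 0.426 with an estimated correlation).

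Glycolysis genes went both ways, and the list did not pass (camera adjusted p = 0.124; median 0.28). Of 21 measured, 8 rose, 4 fell and 9 did not pass (10 and 4 adjusted over the list alone): SLC16A1, a lactate transporter, rose by 2.20 ± 0.35 and LDHA, lactate dehydrogenase, by 1.54 ± 0.57, while ENO2, the neuronal enolase, fell by 1.86 ± 0.28 and ALDOC, an aldolase, by 0.94 ± 0.14. Of 14 measured G1 cyclins and inhibitors, 6 rose, 3 fell and 5 did not pass (6 and 3 adjusted over the list alone; camera adjusted p = 0.281). CCND2, a cyclin of cell cycle entry, rose by 2.79 ± 0.55 and GADD45B by 2.08 ± 0.51, while the cyclin-dependent kinase inhibitors CDKN2D and CDKN1B fell by 1.37 ± 0.38 and 1.34 ± 0.07. Proliferation genes rose in 5, fell in 6 and did not pass in 11 of 22 measured (5 and 6 adjusted over the list alone; camera adjusted p = 0.682; median -0.07, or -0.11 without FKN). CCNE1, a cyclin of S phase entry, rose by 0.82, and CENPF and AURKA, mitotic genes, fell by 0.85 and 0.51. The 5 include MCM2 (0.59), whose probe the files place on chromosome 11; whether it measures that gene was not tested.

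Genes of quiescence and lymph node homing fell in 11 of 24 measured members, rose in 3 and did not pass in 10 (12 and 3 adjusted over the list alone). PIK3IP1 and TSC22D3 fell most, and SATB1, a chromatin organiser, and BTG1, an inhibitor of proliferation, rose by 1.88 ± 0.31 and 0.91 ± 0.32. The list median was -0.46, with camera adjusted p = 0.00763 and adjusted p = 0.426 with an estimated correlation. Genes of T cell identity and receptor signalling fell in 9 of 23, rose in 5 and did not pass in 9 (10 and 6 adjusted over the list alone; camera adjusted p = 0.281; median -0.21). CD27, a costimulatory receptor, fell by 1.78 ± 0.22 and TRAF3IP3 by 1.62 ± 0.55, while SLA, an adaptor that limits receptor signalling, rose by 1.93 ± 0.15 and CD3D, a chain of the CD3 complex, by 0.89 ± 0.33. CD3E of the same complex had -0.20 ± 0.12 (SD, n = 4; limma adjusted p = 0.0589).

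Of the coreceptors, CD4 had a log2 ratio of 0.05 ± 0.04 (SD, n = 4; limma adjusted p = 0.418) and CD8B rose by 0.23 ± 0.11 (adjusted p = 0.0399), with 1 of 2 measured genes also passing adjusted over the list alone; with only 2 measured genes the list was not tested, and CD8A was not analysed here. Cytotoxic effector genes rose in 5, fell in 3 and did not pass in 9 of 17 measured (8 and 4 adjusted over the list alone; camera adjusted p = 0.229; median 0.22, or 0.04 without FTV). GZMB, a granzyme of cytotoxic granules, rose by 1.62 ± 0.56 and HOPX by 1.15 ± 0.59, while GZMK, another granzyme, fell by 0.85 ± 0.10 and FGFBP2 by 0.57 ± 0.31. Apoptosis regulators rose in 8, fell in 3 and did not pass in 6 of 17 (8 and 3 adjusted over the list alone; camera adjusted p = 0.229; median 0.13, or 0.22 without FTV). BCL2L1, which blocks apoptosis, rose by 1.91 ± 0.83 and the death receptor FAS by 1.45 ± 0.23, while BAD, which promotes apoptosis, fell by 0.89 ± 0.23 and CASP8, an initiator caspase, by 0.79 ± 0.45.

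Interferon-stimulated genes, the antiviral programme induced by interferons, mostly did not pass: of 31 measured, GBP1 (2.62 ± 0.73), GBP2 (1.02 ± 0.51) and BST2 (0.82, chosen after its values were seen) rose, IRF9 fell by 0.34, and 27 did not pass (2 rose and 0 fell adjusted over the list alone). The list did not pass (camera adjusted p = 0.966), and its median of -0.19 and mean of 0.06 differed in sign, with the test on the lower side. The median response was 0.30 in FNV, 0.16 in FKN, 0.11 in FBR and -0.81 in FTV. Without FTV the median was 0.11 (camera adjusted p = 0.0164; adjusted p = 0.329 with an estimated correlation).

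**Figure D2:**
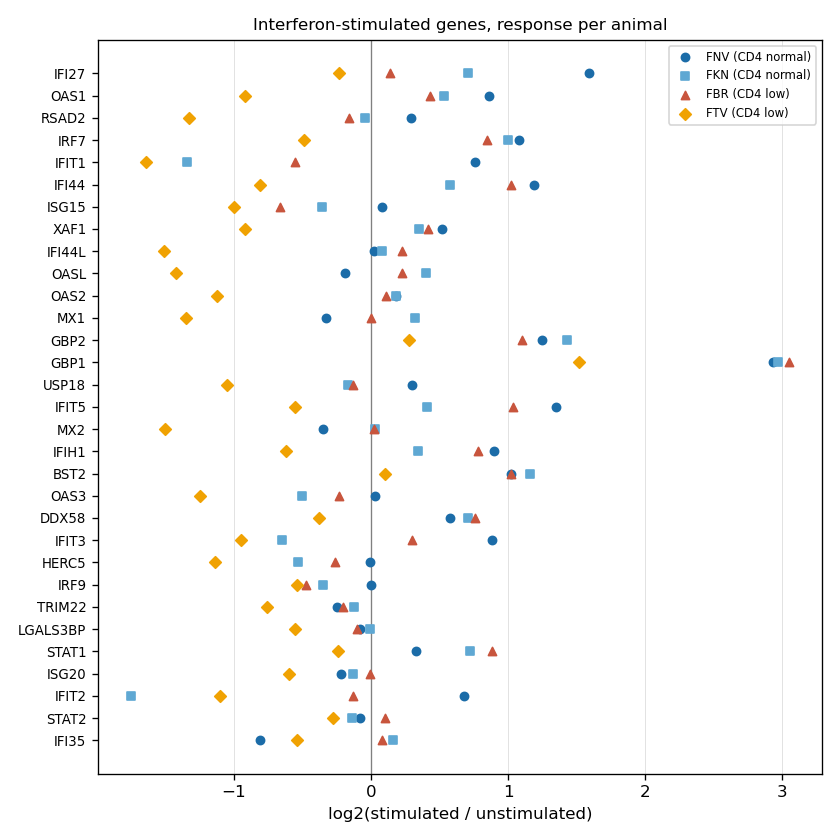
Log2 ratio of stimulated over unstimulated RNA (x axis) of the 31 measured interferon-stimulated genes (y axis), with 1 symbol per animal, sorted by the difference between the CD4-low and CD4-normal animals. FTV has the lowest response in most genes, with a list median of -0.81 against 0.11 in FBR.

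Markers of other blood cell types were measured beside these groups. Monocyte markers fell in 6 of 18 measured genes and 12 did not pass (6 adjusted over the list alone), among them VCAN, a matrix proteoglycan (-1.14 ± 0.53), and the calcium-binding S100A8 (-0.97 ± 0.20). The list median was -0.60, or -0.23 without FNV (camera adjusted p = 0.00335; adjusted p = 0.426 with an estimated correlation). Per animal it was -1.32 in FNV, -0.57 in FKN, -0.24 in FBR and -0.23 in FTV, and with no pairing by animal (no replicate block) the adjusted p was 0.0722. B cell markers fell in 7 of 14 measured genes, rose in 1 and did not pass in 6 (8 and 1 adjusted over the list alone). CD79B, a chain of the B cell receptor complex, fell by 2.60 ± 0.42 and the complement receptor CR2 by 2.49 ± 1.15, while FCER2 rose by 0.36 ± 0.13. The B cell list had a median of -0.22 and camera adjusted p = 0.0258 (adjusted p = 0.405 with an estimated correlation), and the median was -1.18 with the scanner software's ratios, -0.37 with the filter in all 4 animals and -0.45 with every probe. Per the labels the cells had been depleted of CD4, CD8 and CD16 cells, selected for CD3 and used at a purity above 98%.

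NK cell markers rose in 1 gene, XCL1, which T cells also make, fell in 2, the adaptor TYROBP (-0.94 ± 0.29) and the Fc receptor FCGR3A (-0.24 ± 0.13), and did not pass in 5 of 8 (1 and 2 adjusted over the list alone; camera adjusted p = 0.721). The median of this list, -0.08 (-0.03 without FNV), and its mean, 0.28, differed in sign, and the test lay on the lower side. Of 6 measured markers of gamma-delta, NKT and MAIT cells, the receptor gene TRDC (0.46 ± 0.21) and CD160 (0.84 ± 0.66, adjusted p = 0.0499) rose, SOX13 fell by 0.80 and 3 did not pass (2 and 1 adjusted over the list alone). Its median of -0.08 (-0.02 without FBR, -0.13 without FTV) and mean of -0.01 lay below 0 and the camera test on the higher side (adjusted p = 0.999). Dendritic cell markers rose in 1 of 11, LAMP3 (0.42 ± 0.09), with 10 not passing (1 adjusted over the list alone; camera adjusted p = 0.719; median -0.10, or -0.01 without FNV). In the platelet list, TREML1 had the smallest p, with -0.16 ± 0.13 (SD, n = 4; limma adjusted p = 0.123), and none of the 7 measured genes passed (0 adjusted over the list alone; camera adjusted p = 0.281; median -0.12, or -0.19 without FNV and -0.04 without FKN). In the red cell list, HBA2, an alpha globin, fell by 0.23 ± 0.05 and 3 of 4 did not pass (1 adjusted over the list alone; camera adjusted p = 0.26; median -0.17).

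Housekeeping controls rose in 4 of 12 measured genes, fell in 1 and did not pass in 7 (4 and 1 adjusted over the list alone; camera adjusted p = 0.169; median 0.13, or 0.23 without FNV and 0.08 without FKN). TFRC, the transferrin receptor, which was also among the activation markers, rose by 2.43 ± 0.96, PGK1, a glycolytic enzyme, by 0.82 ± 0.16, and RPL13A, a ribosomal protein gene, fell by 0.30 ± 0.08. Over all 30 tested lists, camera with a preset correlation called 17, 14 higher and 3 lower (quiescence, B cell and monocyte markers). With an estimated correlation camera called 0, with 4 at an unadjusted p under 0.05. That setting also has few degrees of freedom with 4 animals, so its 0 does not decide between correlated genes and low power. The fry test, which tests a list on its own and not against other genes, called 21, including all 17 in the same direction.

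**Figure D3:**
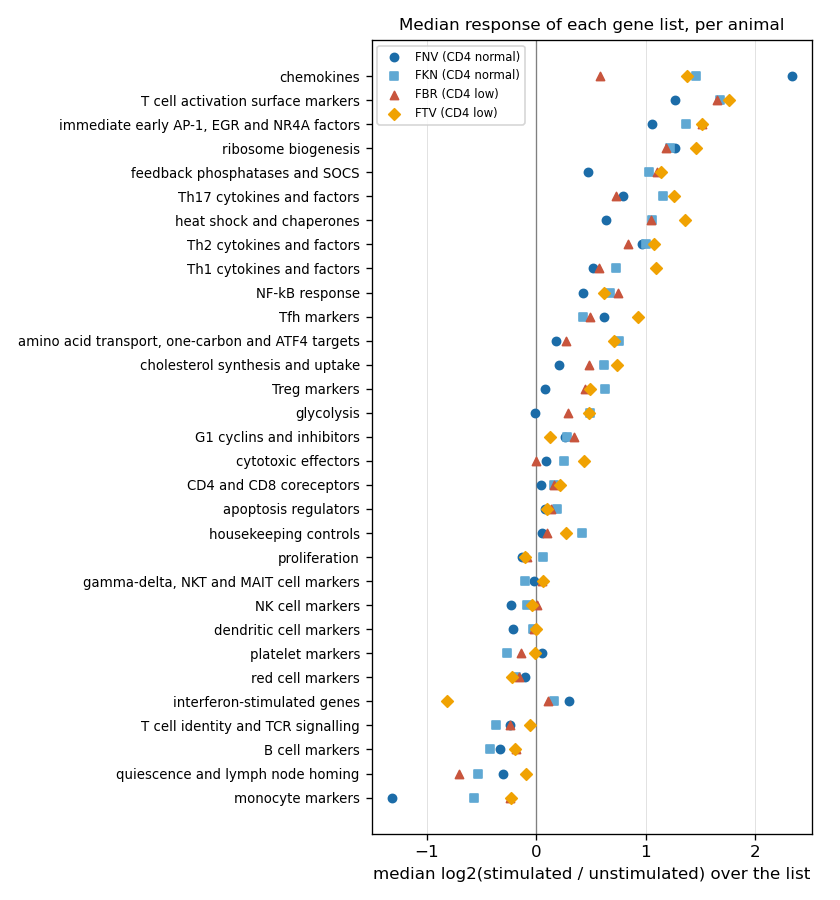
Median log2 ratio of stimulated over unstimulated RNA over the measured genes of each of the 31 lists (x axis; y axis, the lists), with 1 symbol per animal. All 4 animals lie above 0 for ribosome biogenesis (1.19 to 1.46) and below 0 for monocyte markers (-1.32 to -0.23), and FTV lies apart at -0.81 for interferon-stimulated genes.

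The second comparison asked whether the response to stimulation differed between the animals with low and with normal CD4 status. EDN1, the vasoconstrictor endothelin, had the smallest p: its log2 response was 3.45 in FNV and 3.29 in FKN against 1.54 in FBR and 1.52 in FTV, a difference (low minus normal) of -1.84 ± 0.13 (SE, n = 2 against 2; limma adjusted p = 1). C19H19orf59 differed by 1.31 ± 0.15 and the lectin receptor gene CLEC4A by 1.22 ± 0.16, both with smaller falls in the animals with low CD4 status (adjusted p = 1 for both). CD4 itself differed by 0.04 ± 0.12 and CD8B by 0.14 ± 0.13. In limma 0 of 22655 features passed, and 485 had an unadjusted p under 0.05, fewer than chance alone would give.

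Fitting the 8 arrays with the animal as a random block in limma gave 3 features lower in the low group. They were EDN1 (adjusted p = 0.00873), the potassium channel gene KCNJ2 (-1.48, adjusted p = 0.031, chosen after its values were seen) and an unnamed probe (-2.00, adjusted p = 0.0309). The 2 arrays of an animal repeat the same 2 RNAs, so these p-values rest in part on technical spread and not on more animals. Within the later scan batch, with FKN alone as the normal animal, the differences were -1.76 for EDN1, 1.18 for C19H19orf59 and 1.11 for CLEC4A (adjusted p = 1 for each).

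The third comparison asked whether levels differed with CD4 status in unstimulated cells. The elongation factor gene EEF1D was at a normalised log2 level of 8.53 in FBR and 9.32 in FTV, against 11.99 in FNV and 12.01 in FKN, a difference of -3.08 ± 0.33 (SE, n = 2 against 2; limma adjusted p = 0.839). VMO1 differed by -2.72 ± 0.32 and Mamu-DRB1, a class II histocompatibility gene, by -2.04 ± 0.24 (adjusted p = 0.839 for both). Their differences within the later scan batch were -3.08, -2.50 and -1.86. Whether the rhesus probes match the mangabey sequence alike in every animal was not tested for these genes. CD4 differed by 0.05 ± 0.24 and CD8B by -0.34 ± 0.30, or by 0.17 and -0.03 within the later batch. In limma 0 of 22655 features passed and 384 had an unadjusted p under 0.05, fewer than chance alone would give. Without FTV, which leaves FBR as the lone low animal, the Y-linked ribosomal protein genes RPS4Y2 and RPS4Y1 differed by -8.38 and -7.33. Both were well above background in 4 of 4 channels of each animal and low in FBR alone. RPS4Y2 was 6.64 in FBR against 14.56 to 15.34 in the other animals, and RPS4Y1 was 8.02 against 14.83 to 15.73. These 2 genes set FBR apart as a difference in sex would, so sex may be unbalanced between the CD4 groups. Sex was not a term in the CD4 comparisons and was not tested otherwise. With the animal as a random block over 8 values 1 unnamed probe passed (4.23). These genes and this probe were chosen after their values were seen.

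In stimulated cells EEF1D differed by -2.89 ± 0.30 (low minus normal, SE, n = 2 against 2), RAB30, a small GTPase gene, by -1.92 ± 0.22 and VMO1 by -2.04 ± 0.25 (limma adjusted p = 0.841 for each). Within the later scan batch these were -3.00, -1.89 and -2.08. CD4 differed by -0.07 ± 0.29 and CD8B by -0.08 ± 0.22, or by 0.23 and 0.06 within the later batch. In limma 0 of 22655 features passed and 497 had an unadjusted p under 0.05, fewer than chance alone would give. This comparison changed most on leaving out FKN. That leaves FNV, alone in the earlier scan batch, as the lone normal animal, so CD4 status and scan batch cannot be told apart in that fit. With the animal as a random block over 8 values the same unnamed probe as in unstimulated cells passed (4.29).

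The self-self arrays gave the dye effect, the log2 ratio of Cy5 over Cy3 when both channels held the same RNA. In limma 2556 features departed from 0, 1401 towards Cy5 and 1155 towards Cy3, and only 2 of them by 2-fold or more. The count was 763 without FKN and 451 without FBR, and 4842 with no background subtraction. Leaving out spots far below their local background, a choice made after the data were seen, gave 4469. The stimulation response of the 8 ratio arrays averaged the dye orientations of each animal, and the log2 ratios of the paired arrays correlated across features at -0.91 in FNV and -0.93 in the others before one was turned (features are not independent replicates).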

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

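The tests of scan batch and CD4 status for FNV, the test of CD4 status for the interferon-stimulated genes and the gene lists in the CD4 comparison of responses were chosen after the results were seen.

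In 8 of 102 named genes and 2 of 30 lists, 1 animal lay far from the other 3, by a gap over range that chance exceeds in about 1 of 20 groups. For TFRC the gap over range was 0.922 (log2 response 0.99 in FNV, 2.85 to 3.00 in the others) and for CR2 it was 0.836 (-0.77 in FNV, -3.24 to -2.84 in the others). FNV was also the distant animal for SYTL2 (0.951), the cystine transporter gene SLC7A11 (0.871), TNIP3 (0.841), the feedback phosphatases and SOCS list (0.836; median 0.47 against 1.03 to 1.14) and the dendritic cell list (0.857; -0.21 against -0.03 to 0.00), which made 7 of the 10 cases. GBP1, an interferon-induced GTPase, stood apart in FTV (0.922; 1.52 against 2.93 to 3.05), AURKA in FBR (0.855) and BIRC3 in FKN (0.852; 1.37 against 2.29 to 2.45).

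The response of FNV stood apart from that of the other 3 animals, with correlations across features of 0.73, 0.75 and 0.68 with FKN, FBR and FTV, while those among the other 3 were 0.88 to 0.91. Lower signal on its arrays is argued against as the whole cause, because over the brightest features on its ratio arrays its mean correlation was 0.79, up from 0.72 over all features but below the lowest of the others, 0.91. CD4 status is argued against as well, since FKN, which shares it, correlated with FNV less than with the animals with low status, by -0.18. The scan batch cannot be told apart from the animal, as only 1 animal was in the earlier batch.

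For the count of 9081 features in the stimulation response, the 8 distinct sign assignments of the 4 animals are too few for a share under 0.05. The real assignment was the only 1 to reach that count, and the highest of the others gave 0. For dye bias left after averaging the dye flip, the self-self arrays were used, where dye and condition are separate. Their change in level correlated with the ratios of the passing features at 0.99. Large changes weigh most in that value and only 2 dye effects reached 2-fold, so it argues against dye bias for large changes and cannot decide for small ones. On the self-self arrays alone, 6411 of the 9081 features passed in the same direction and 0 in the opposite one.

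Tested with camera at a preset correlation, 8 lists differed between CD4-low and CD4-normal animals in their response. The Th1 list was higher in the low animals (median difference 0.31, adjusted p = 0.000146), as were immediate early factors (0.40, 0.00138), monocyte markers (0.63, 0.00363), feedback phosphatases and SOCS (0.37, 0.00503), heat shock proteins (0.22, 0.0169), cholesterol genes (0.22, 0.0254) and glycolysis genes (0.21, 0.0282). Monocyte markers had a median below 0 in each animal (-1.32 in FNV and -0.57 in FKN, -0.24 in FBR and -0.23 in FTV). For them higher therefore means a smaller fall. Their unstimulated level differed by -0.68 (low minus normal, median over the list), or by -0.13 without FNV. Interferon-stimulated genes were lower in their response (-0.64, 2.29e-10). With an estimated correlation each of the 8 lists had adjusted p = 0.983. With 2 animals against 2 that setting has very few degrees of freedom, so it can hardly call a list. Without FNV the median differences were 0.22 for immediate early factors, 0.21 for monocyte markers, 0.10 for feedback phosphatases and SOCS, 0.05 for heat shock proteins, 0.04 for cholesterol genes and 0.10 for glycolysis genes, and without FTV they were 0.24, 0.68, 0.22, 0.06, 0.04 and 0.10. Heat shock, cholesterol and glycolysis genes had 0.38, 0.37 and 0.36 without FKN, and without FBR heat shock and cholesterol genes had 0.39 and 0.46 and interferon-stimulated genes -1.12. With the scanner software's ratios the difference was 0.05 for immediate early factors, 0.34 for monocyte markers and 0.15 for the Th1 list. Median centring, which moved the median over all features from 0.02 to 0.19, gave 0.67 for Th1, 0.66 for feedback phosphatases and SOCS, 0.59 for heat shock proteins, 0.51 for cholesterol genes, 0.54 for glycolysis genes and -0.33 for interferon-stimulated genes. The Th1 medians per animal overlapped between the groups, with 0.52 in FNV and 0.73 in FKN against 0.57 in FBR and 1.09 in FTV. In the same order, overlap was also seen for glycolysis genes (-0.01 and 0.49 against 0.29 and 0.48) and cholesterol genes (0.21 and 0.62 against 0.48 and 0.74). Heat shock proteins overlapped too (0.64 and 1.06 against 1.05 and 1.36), while the medians of the other called lists did not. At the preset correlation only the Th1 call held with each animal left out in turn: 3 of the 8 held without FNV (Th1, immediate early and interferon-stimulated) and 2 without FTV (Th1, with 0.38, and monocyte markers, with 0.68).

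The lower response of interferon-stimulated genes in the CD4-low animals covered 29 of 31 genes. Of the 31, 9 had both low animals below both normal ones and 0 the reverse (16.7% each way by chance for 1 gene). FTV had the lowest response in most of them, so the genes are not independent observations and these counts are no test. A difference between scan batches is argued against, since the median difference was -0.47 without FNV. A higher unstimulated level in the low animals may account for it: the level of the list was 1.13 higher, 0.85 without FNV, and 1.16 on the self-self arrays, which are other hybridisations of the same RNA, although response and level share that RNA. This rested on FTV, whose unstimulated level on those arrays lay 1.40 above the mean of the animals against -0.26 in FBR, and without FTV the difference in response was 0 (camera adjusted p = 0.538). Whether CD4 status or another trait of FTV lies behind it cannot be told apart with 1 low animal left.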

How the results depend on the processing

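The results with high-background spots left out and with scan batch as a term were added after the data were seen. The passing direction of features in the stimulation response turned in 0 cases under each setting, while the count of 9081 moved to 4048 with median centring (38.6% higher against 47.7%), and to 4868 to 11390 on leaving out 1 animal. On the self-self arrays it was 6842 paired and 1946 unpaired (no replicate block), or 6834 and 1923 with high-background spots left out; unpaired, the monocyte list (adjusted p = 0.0722) and 37 named genes no longer passed. The count of 2-fold changes, 1545, was 3295 with the scanner software's ratios, 976 with no replicate block and 1363 to 1864 without 1 animal. Of the gene lists, 17 were called, 16 to 20 under the other camera settings, 17 to 18 without 1 animal, 21 by fry and 0 with an estimated correlation, also without each animal (a choice made after the data were seen). The interferon-stimulated list turned higher without FTV (median 0.11, adjusted p = 0.0164; adjusted p = 0.329 with an estimated correlation), and its median without FNV was -0.25. The CD4 comparison of responses gave 0, or 3 with the animal as a random block, and 0 to 0 without 1 animal. The CD4 comparison of unstimulated levels gave 0, or 1 with the random block and 0 to 2 without 1 animal, and that of stimulated levels 0, 1 and 0 to 3416. The dye effect, 2556, was 4842 with no background subtraction, 4469 with high-background spots left out and 451 to 2422 without 1 animal. For named genes of the stimulation response, 1747 comparisons over all settings kept direction and side of the threshold, 160 lost the threshold, 2 gained it and 0 turned; 21 values moved by more than the SD between animals in the authors' deposited table. The cause of these shifts was not tested. Signal over background limits FNV most, with 33.3% of spots well above background in a channel of its stimulated self-self array.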

Other observations

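The genes named here were chosen after their values were seen, except FOXP3 and IL2, which were fixed by name for the stimulation response, and SATB1 and TSC22D3, which the rule named; the difference of IL2 by CD4 status was chosen after its values were seen.

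Of the transcription factors of T cell lineages, TBX21, the factor of Th1 cells, rose by 0.37 on the log2 scale (limma adjusted p = 0.0269) and RORA, a nuclear receptor, by 1.07 (0.00184). GATA3 of Th2 cells had 0.42 (0.0628), BCL6 of follicular helper cells 0.41 (0.0985) and FOXP3 0.03 (0.634). IRF4 (2.06, adjusted p = 0.000725) and BATF (2.27, 0.00144), which act together in several effector lineages, rose, as did MYC (2.07, 0.00154), a driver of cell growth. Differences between these genes were not tested.

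The chemokine genes CXCL10 and CXCL9, ligands of CXCR3, rose by 3.13 (limma adjusted p = 0.0025) and 2.95 (0.00313), and the transcription factor gene IRF1 by 0.90 (0.0211). The antiviral genes MX1 (-0.34, adjusted p = 0.361), ISG15 (-0.49, 0.0823) and OAS1 (0.23, 0.567) did not pass, and no difference between these genes was tested. Transcriptional regulators on the quiescence list went both ways: ID3 fell by 2.45 (0.000747), TCF7 by 1.17 (0.0134), LEF1 by 1.05 (0.000774) and FOXO3 by 0.47 (0.0104), as did TSC22D3, while SATB1 rose by 1.88 (0.000766) and BACH2 by 0.68 (0.029). FOXP1 (0.36, adjusted p = 0.226), FOXO1 (-0.34, 0.136), KLF3 (-0.26, 0.129) and KLF7 (-0.05, 0.472) did not pass.

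The response of IL2 was 3.61 in FNV and 2.99 in FKN, the animals with normal CD4 status, against 6.44 in FBR and 5.29 in FTV, a difference of 2.57 ± 0.46 (SE, n = 2 against 2; limma adjusted p = 1).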
